A study of Mus musculus with 12 samples.

How the data were processed

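RNA was profiled from LysoDCs, the lysozyme-expressing dendritic cells of Peyer's patches, the lymphoid follicles of the small intestinal wall. Per the labels' protocols, WT and Gpr31b-deficient mice were left uninfected or given Listeria monocytogenes strain EGDe by mouth. Peyer's patch cells were released with collagenase D and DNase I at day 2 after infection, and LysoDCs were sorted on a BD FACSAria II. RNA was extracted with an RNeasy Mini kit and amplified into libraries with a SMART-Seq HT PLUS kit, per the labels' protocols. There were 4 groups of 3 libraries, each genotype with and without infection, and the labels number the mice 1 to 3 within every group. Each library was treated as a separate mouse.

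The authors deposited raw counts per Ensembl gene, 55416 genes in 12 columns, with no normalization. Per the submitters' processing notes, fastp, HISAT2, featureCounts and the mouse build GRCm39 were used. Their versions, the annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be separated, and values of genes with near-identical copies are uncertain. Every column matched 1 sample by its name. Gene symbols, biotypes, exon lengths, chromosomes and transcript sequences came from the GENCODE annotation of the earlier build GRCm38, matched by gene ID. A symbol was found for 52083 IDs, and no coordinates were used because the builds differ.

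Total counts per library ran from 3521311 to 5959544, and 34240 to 40492 genes had at least 1 count. Genes were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors and the quasi-likelihood F test. All 12 libraries entered one fit, with the 4 groups as the only term, so each gene had 1 dispersion for all groups. The filter kept 26620 genes. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Infection was tested in WT and in KO, and genotype (KO against WT) in uninfected and in infected libraries. Genotype averaged over infection and the interaction (infection effect in KO minus that in WT) completed the 6 contrasts. The common biological coefficient of variation was 0.519, with a median of 0.292 over the 11189 genes with a mean of at least 10 CPM (counts scaled to a fixed total per library). The fit had 8 residual degrees of freedom and a median of 9.26 prior ones. CPM of named genes use TMM-scaled library sizes unless total counts are named. Errors of log2 fold changes are standard errors, and errors of levels are SDs over n = 3.

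Gene lists of pathways and of cell types that such a sort could hold, 38 in all, were fixed before the data were examined, as were the contrasts, the alternatives and the rule for named genes. The 36 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, and p-values were adjusted over the lists. Camera with an estimated correlation and the directional fry test served as alternatives. Members were also adjusted over the list alone. List scores per library are mean log2(CPM + 1) over the members. Immunoglobulin and T cell receptor segments were summed as a share of counts. Counts over 1500 sensory receptor genes, which dendritic cells are not known to express, served as a measure of background reads.

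The named genes were, per contrast, up to 8 per direction with the largest fold changes among called genes with at least 10 CPM, without predicted genes and receptor segments. Their libraries had to be free of overlap between the groups, except for the averaged effect and the interaction. From each list that passed or held a called gene, up to 4 members with the smallest p were added, and up to 2 from the other lists. The Gpr31 genes were always named. Where fewer than 10 genes were called, all of them and those of smallest p up to 10 were named. Alternative scalings were the size factors of DESeq2 (RLE) and upper-quartile factors, and alternative filters were none and 5 CPM in 3 libraries. Alternative tests were the Wald test of DESeq2 1.42.0, limma-voom with quality weights, robust empirical Bayes, a fit of only the groups compared and a replicate block. Receptor segments were also left out, as was each library in turn. Chosen after seeing the data were a mean of at least 30 CPM, marker scores as covariates and a test without the genes of chromosome 17. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for exact tests and figures, and BLAST 2.17.0 for matches between transcripts (at least 95% identity over at least 100 bases).

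The gene test was tested on simulated data for infection in WT, with counts of 25101 genes drawn at the real means and library sizes. Of genes with at least 10 CPM, 8 of 75 changed 2-fold (10.7%) and 53 of 75 changed 4-fold (70.7%) were recovered. Under 10 CPM, 0 of 25 and 2 of 25 (8%) were recovered, and 1 of 64 calls was false. The unchanged genotype contrast in uninfected libraries gave 0 calls. A list raised 1.5-fold in the same contrast (25144 genes) reached an adjusted p of 2.78e-13, and 0 lists without shared members passed. Genes were drawn independently of each other, so the simulation cannot show how often camera passes lists of correlated genes. All groups had the same dispersion per gene, so it cannot show errors or recovery where groups differ in spread. At this depth and number of mice, changes of 2-fold and genes of low level would mostly be missed.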

Results

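LysoDCs of Peyer's patches were profiled by RNA sequencing in 4 groups of 3 libraries, from mice WT or Gpr31b-deficient, uninfected or at day 2 after oral Listeria monocytogenes. The study asked how signalling through GPR31, a receptor for bacterial metabolites such as lactate and pyruvate, affects gene expression of these cells during infection. Libraries held 3521311 to 5959544 counts. The median correlation of a library with its own group ran from 0.921 to 0.938 in KO and from 0.859 to 0.874 in WT. With the other groups it ran from 0.874 to 0.901 in KO and from 0.859 to 0.896 in WT. Every KO library lay closer to its own group than to the others. Among WT libraries only infected replicate 2 did (0.874 against 0.865), so WT replicates were less alike than KO ones. These are Pearson values of log2 CPM across the 11189 genes with at least 10 CPM, which are not independent replicates. Transcripts of B lineage cells were present in every library. Immunoglobulin and T cell receptor segments took 0.800 ± 0.505% in WT uninfected, 1.40 ± 0.824% in WT infected, 0.199 ± 0.0831% in KO uninfected and 0.189 ± 0.101% in KO infected libraries (SD, n = 3). Of 1500 sensory receptor genes, taken as background, 62.3 to 71.0% had at least 1 count in WT and 70.6 to 81.9% in KO libraries. Their counts, as CPM per kb, were 0.483 to 0.992 in WT and 0.673 to 1.12 in KO. A difference in background between genotypes was not tested, and it could affect calls of genes with low counts.

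The targeted gene, Gpr31b (ENSMUSG00000071311, chromosome 17), had 14, 27 and 14 counts in the WT uninfected libraries and 20, 27 and 12 in KO uninfected. It had 38, 40 and 41 in WT infected and 6, 25 and 14 in KO infected libraries. As CPM of total counts these were 4.70 ± 2.43, 5.07 ± 1.68, 8.89 ± 1.96 and 3.47 ± 2.61 in the same order (SD, n = 3). The genotypes overlapped in uninfected libraries (exact two-sided permutation p = 0.8). In infected libraries all KO values lay below all WT values (exact p = 0.1, the smallest that 3 against 3 allows). Gpr31b lay above 70.2 to 99.5% of 382 sensory receptor genes of similar exon length in the same library. Its paralogue Gpr31a (ENSMUSG00000116935) stood at 2.97 ± 1.67 and 4.21 ± 0.912 CPM in WT and KO uninfected libraries (exact p = 0.4), and at 4.58 ± 2.43 and 1.78 ± 0.914 in infected ones (exact p = 0.2). The part of the gene that was deleted was not given in the sources used here, so transcript counts need not fall. The genotypes below are those of the labels.

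Infection in WT mice raised groups of genes by camera, while no single gene passed the test. Interferon-stimulated genes, the programme driven by type I interferon, rose with 34 of 39 members positive (median log2 fold change 0.40, adjusted p = 3.02e-05). Immediate early genes, which respond to stimulation and to tissue dissociation, rose with 24 of 30 positive (median 0.45, adjusted p = 2.42e-05). The LysoMac and resident macrophage list rose (median 0.51, adjusted p = 0.00241). In it the complement genes C1qc and C1qb stood at 1.40 ± 0.32 and 1.28 ± 0.31 log2, and the lipid carrier Apoe at 1.29 ± 0.33. Lysosomal hydrolase genes rose (median 0.28, adjusted p = 6.33e-05), with the protease Ctsb at 0.68 ± 0.16. Beside these groups the B cell list rose (median 0.67, adjusted p = 1.43e-05), its score going from 5.68 ± 0.58 to 6.11 ± 0.36 (SD, n = 3). With an estimated correlation, the adjusted p of these lists ran from 0.446 to 0.484. The type I interferon list had a median of 0.22 without WT infected replicate 3. The immediate early list had a median of 0.18 without WT infected replicate 3. The macrophage list had a median of 0.22 without WT infected replicate 2. The B cell list had a median of 0.35 without WT uninfected replicate 2. The share of mitochondrial counts was 0.689, 0.758 and 0.268% in the WT infected libraries, the ribosomal score 8.08, 8.28 and 7.38 and the immediate early score 7.47, 7.40 and 7.96 (replicates 1 to 3).

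The immediate early transcription factors Egr1 and Fos differed by 2.07 ± 0.46 (adjusted p = 0.224) and 0.85 ± 0.19 (adjusted p = 0.224), short of the threshold. So did the fractalkine receptor Cx3cr1 at 1.95 ± 0.40 (adjusted p = 0.211), the interferon-inducible Ifi27l2a at 1.40 ± 0.30 (adjusted p = 0.211) and the actin gene Actb at 1.11 ± 0.19 (adjusted p = 0.189). Interferon-gamma response genes rose with 31 of 40 positive (median 0.42, adjusted p = 0.00408), and genes of MHC class I presentation rose (median 0.23, adjusted p = 6.33e-05), with the peptide transporter Tap1 at 0.68 ± 0.22. Further lists that rose were inflammatory cytokines (median 0.33, adjusted p = 0.0351), NF-kB targets (median 0.23, adjusted p = 0.0119), plasma cell genes (median 0.44, adjusted p = 0.0279) and cholesterol efflux (median 0.28, adjusted p = 0.0119). Dendritic cell maturation (median 0.19, adjusted p = 0.00205), autophagy (median 0.17, adjusted p = 0.00818), LysoDC identity (median 0.14, adjusted p = 0.0279), MHC class II presentation (median 0.19, adjusted p = 0.0351) and inflammasome genes (median 0.19, adjusted p = 0.0351) rose by less. For these 11 lists, an estimated correlation gave an adjusted p of 0.446 to 0.498. Random lists matched on mean level had medians of 0.15 (maturation), 0.14 (autophagy), 0.13 (LysoDC identity), 0.16 (MHC class II) and 0.13 (inflammasome). The medians of these lists lay within the matched range. Adjusted over the list alone, 5 macrophage genes were higher and 1 lower. By the same count, 3 cholesterol efflux genes, 2 immediate early genes and 1 interferon-stimulated gene were higher. List medians were 0.19 (cytokine), 0.0897 (MHC class II), 0.42 (maturation), 0.23 (LysoDC identity) and 0.11 (cholesterol efflux) without WT infected replicate 3. Leaving out WT infected replicate 2 gave medians of 0.36 (NF-kB), 0.24 (plasma cell) and 0.30 (inflammasome). With WT uninfected replicate 2 left out, the medians were 0.32 (maturation), 0.28 (LysoDC identity) and 0.29 (inflammasome). The NF-kB list had a median of 0.15 without WT uninfected replicate 1. The maturation list had a median of 0.34 without WT uninfected replicate 1. The LysoDC identity list had a median of 0.28 without WT infected replicate 1. The plasma cell list had a median of 0.71 without WT infected replicate 1.

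By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 26620 genes changed with infection in WT. At an unadjusted p under 0.05 there were 2339, where 1331 would fall by chance, and other tools called 146 with DESeq2 and 0 with limma-voom. The groups shared each gene's dispersion, while WT replicates were less alike than KO ones. The unadjusted count in WT may therefore be too high, and it cannot be compared with that in KO. The groups did not overlap for 3124 genes, 11.7% where chance gives 10%. Of the 36 lists, 16 rose by camera and 0 passed with an estimated correlation or by fry. Leaving out WT infected replicate 3 gave 11 called genes, and leaving out WT infected replicate 1 gave 4. Without WT infected replicate 3 the cytokine (0.124), NF-kB (0.102), plasma cell (0.0776) and immediate early lists (0.0526, adjusted p) were lost. So were the inflammasome (0.125), autophagy (0.0791) and cholesterol efflux lists (0.0641). Without WT uninfected replicate 1 the NF-kB (0.216), MHC class II (0.315), LysoDC identity (0.112) and inflammasome lists (0.122) were lost. The cytokine list was also lost without WT uninfected replicate 2 (0.0727) or 3 (0.0511). MHC class II was lost without WT uninfected replicate 3 (0.0511) or WT infected replicate 2 (0.0519), and plasma cell genes without WT uninfected replicate 2 (0.171) or WT infected replicate 2 (0.255).

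Infection in KO-labelled mice raised interferon, immediate early and inflammatory lists by camera, while KO infected replicate 2 stood apart from its group. Immediate early genes rose with 25 of 30 members positive (median 0.66, adjusted p = 7.35e-19), and 17 members were higher and 2 lower when adjusted over the list alone. Fos went from 799 ± 63.3 to 2002 ± 278 CPM (SD, n = 3), a log2 difference of 1.33 ± 0.19 (adjusted p = 0.0578) that missed the threshold over all genes. Type I interferon-stimulated genes rose with 37 of 39 positive (median 0.67, adjusted p = 5.68e-13), and interferon-gamma response genes with 36 of 40 positive (median 0.62, adjusted p = 1.82e-10). Inflammatory cytokine genes rose (median 0.56, adjusted p = 2.88e-05), 3 of them when adjusted over the list alone. Cxcl2, which attracts neutrophils, differed by 2.20 ± 0.50 and the prostaglandin synthase Ptgs2 by 1.28 ± 0.29, neither past the threshold over all genes. Under an estimated correlation these lists had an adjusted p of 0.143. List medians were 0.37 (type I interferon), 0.12 (interferon-gamma) and -0.00024 (cytokine) without KO infected replicate 2. Scores of the type I interferon list were 4.36, 5.52 and 4.90 in KO infected libraries (replicates 1 to 3) against 4.34, 4.44 and 4.58 in uninfected ones. Those of the interferon-gamma list were 4.66, 5.83 and 4.94 against 4.69, 4.88 and 4.70, and those of the cytokine list 4.35, 5.03 and 4.29 against 4.36, 4.39 and 4.18.

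NF-kB targets rose (median 0.29, adjusted p = 2.88e-05), 4 of them when adjusted over the list alone, with the feedback inhibitors Tnfaip3 at 1.18 ± 0.28 and Nfkbia at 1.26 ± 0.30. Antigen presentation genes rose for MHC class I (median 0.33, adjusted p = 9.85e-07) and class II (median 0.21, adjusted p = 0.000133), with the class II transactivator Ciita at 0.69 ± 0.19. Lysosomal genes (median 0.28, adjusted p = 5.64e-08), pattern recognition receptors (median 0.38, adjusted p = 0.00219), cholesterol synthesis (median 0.35, adjusted p = 2.88e-05) and LysoDC identity genes (median 0.33, adjusted p = 0.000683) rose. Markers of other cells rose beside them, those of conventional dendritic cells 1 (cDC1, median 0.44, adjusted p = 4.17e-05) and of B cells (median 0.30, adjusted p = 0.0116). With an estimated correlation, the adjusted p of these 9 lists ran from 0.143 to 0.549. Glycolysis (median 0.25, adjusted p = 0.00128), oxidative phosphorylation (median 0.21, adjusted p = 0.000132), actin dynamics (median 0.20, adjusted p = 0.000741) and cell cycle genes (median 0.21, adjusted p = 0.000762) rose with small medians. The unfolded protein response (median 0.14, adjusted p = 0.000816), inflammasome (median 0.25, adjusted p = 0.00328), antimicrobial (median 0.17, adjusted p = 0.00427) and cholesterol efflux lists (median 0.22, adjusted p = 0.0148) rose as well. For these 8 lists, an estimated correlation gave an adjusted p of 0.143 to 0.30. Random lists matched on mean level had medians of 0.18 (unfolded protein response), 0.15 (antimicrobial), 0.17 (actin) and 0.19 (oxidative phosphorylation). The unfolded protein response list lay under its matched median, so it did not rise beyond genes of its level. The other 3 lay within the matched range. Leaving out KO infected replicate 2 gave medians of 0.10 (NF-kB), 0.16 (LysoDC identity), 0.00766 (B cell), 0.12 (glycolysis), 0.0563 (cell cycle), 0.14 (inflammasome), 0.0912 (antimicrobial) and 0.11 (cholesterol efflux). The pattern recognition list had a median of 0.24 without KO uninfected replicate 3. The B cell list had a median of 0.18 without KO uninfected replicate 1, 0.53 without KO uninfected replicate 2 and 0.16 without KO uninfected replicate 3. The cell cycle list had a median of 0.35 without KO infected replicate 1.

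With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 26620 genes changed with infection in KO-labelled mice. At an unadjusted p under 0.05 there were 1163 (1331 by chance), and other tools called 15 with DESeq2 and 8 with limma-voom. Because the dispersion was shared with the less alike WT libraries, the unadjusted count and the 0 calls in KO may be too low. The groups did not overlap for 4084 genes, 15.3% where chance gives 10%. Of the 36 lists, 21 rose by camera and 0 passed with an estimated correlation or by fry. Without KO infected replicate 2 the cytokine (0.177), NF-kB (0.191), antimicrobial (0.0755) and B cell lists (0.512, adjusted p) were lost. So were the inflammasome (0.205), pattern recognition (0.0706), cell cycle (0.148) and cholesterol efflux lists (0.205). The B cell list was also lost without KO uninfected replicate 1 (0.201) or 3 (0.0977), and cholesterol efflux without KO uninfected replicate 1 (0.0692). Counts of called genes were 1 without WT infected replicate 2, 2 without WT uninfected replicate 2 and 4 without WT infected replicate 3.

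Between uninfected genotypes, Pim1, a serine/threonine kinase of cytokine signalling (ENSMUSG00000024014, chromosome 17), was higher in the libraries labelled KO. It rose from 47.9 ± 14.7 to 559.9 ± 51.2 CPM (SD, n = 3), a log2 change of 3.55 ± 0.42 (adjusted p = 0.00120). Atp6v0c (ENSMUSG00000024121, chromosome 17), a subunit of the proton pump that acidifies lysosomes, fell from 227 ± 20.8 to 76.2 ± 8.83 CPM, or -1.58 ± 0.17 (adjusted p = 0.000665). Its pseudogene Atp6v0c-ps2 (ENSMUSG00000080242, chromosome 6) rose from 11.6 ± 1.78 to 77.9 ± 4.08, or 2.74 ± 0.24 (adjusted p = 5.92e-05). Both values are uncertain, because the transcripts match at 99.7% over 387 bases. Cr2, the complement receptor of B cells and follicular dendritic cells (ENSMUSG00000026616), fell from 128 ± 35.8 to 42.5 ± 7.77 CPM, or -1.59 ± 0.24 (adjusted p = 0.0182). The remaining calls were the predicted gene Gm9825 at 3.41 ± 0.49 (adjusted p = 0.0127) and Nap1l3, with 0 counts in every WT uninfected library and 6.55 ± 1.86 CPM in KO (adjusted p = 0.0368).

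Marker lists of other cells differed between the uninfected genotypes by camera. The cDC1 list was higher in KO-labelled libraries with 14 of 15 positive (median 1.30, adjusted p = 4.94e-17, and adjusted p = 0.0316 with an estimated correlation), 8 of them when adjusted over the list alone. The chemokine receptor Xcr1, which marks cDC1, differed by 1.82 ± 0.33 (adjusted p = 0.121) and the RNA sensor Tlr3 by 2.82 ± 0.53 (adjusted p = 0.162), short of the threshold over all genes. The B cell list fell with 23 of 25 negative (median -0.86, adjusted p = 7.5e-17), 11 of them when adjusted over the list alone. Plasma cell (median -0.63, adjusted p = 1.18e-07) and cell cycle genes (median -0.49, adjusted p = 2.62e-08) fell. Under an estimated correlation these lists had an adjusted p of 0.242 to 0.262. The B cell scores of the genotypes overlapped, at 6.04, 5.01 and 5.99 in WT and 4.77, 5.26 and 4.65 in KO. Ribosomal proteins (median -0.18, adjusted p = 0.000159), oxidative phosphorylation (median -0.21, adjusted p = 0.000452), cholesterol synthesis (median -0.31, adjusted p = 0.000206) and the unfolded protein response (median -0.14, adjusted p = 0.00271) fell too. With an estimated correlation, the adjusted p of these lists ran from 0.262 to 0.743. Epithelial genes fell (median -0.69, adjusted p = 0.00227), with overlapping scores of 3.57, 2.17 and 2.06 in WT and 2.15, 2.32 and 2.06 in KO (replicates 1 to 3). The lysosomal (median -0.11, adjusted p = 0.0429) and mitochondrially encoded lists (median -0.23, adjusted p = 0.0429) fell, and the immediate early list rose (median 0.18, adjusted p = 0.0412). For these lists, an estimated correlation gave an adjusted p of 0.358 to 0.777. With WT uninfected replicate 2 left out, the medians were -0.11 (ribosomal), -0.0356 (lysosomal) and 0.41 (immediate early). The cell cycle list had a median of -0.24 without WT uninfected replicate 3. The cholesterol synthesis list had a median of -0.0760 without KO uninfected replicate 3. The unfolded protein response list had a median of -0.28 without KO uninfected replicate 2. The epithelial list had a median of -0.12 without WT uninfected replicate 1. The lysosomal list had a median of -0.0316 without KO uninfected replicate 1 and -0.0652 without KO uninfected replicate 2.

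The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 6 of 26620 genes between uninfected genotypes, 4 higher and 2 lower in KO, and other tools 52 with DESeq2 and 4 with limma-voom. Of 36 lists 12 passed, 1 of them with an estimated correlation. Pim1, Atp6v0c and Atp6v0c-ps2 were called with each library left out in turn. Cr2 was lost without WT uninfected replicate 1 or 3, or KO uninfected replicate 1, 2 or 3 (adjusted p from 0.0584 to 0.217). Gm9825 was lost without WT uninfected replicate 3, or KO uninfected replicate 2 or 3 (adjusted p from 0.0510 to 0.0984). Nap1l3 was lost without WT uninfected replicate 1, 2 or 3, KO uninfected replicate 1, 2 or 3, or KO infected replicate 1 or 3 (adjusted p from 0.0659 to 0.154). Gene counts were 3 without WT uninfected replicate 3, or KO uninfected replicate 2 or 3, and 3 without the genes of chromosome 17, an alternative chosen after seeing the data. The epithelial list was lost without WT uninfected replicate 1 (adjusted p = 0.632), and the immediate early list without WT uninfected replicate 1 or 3, or KO uninfected replicate 3 (adjusted p from 0.139 to 0.435). The lysosomal list was lost without WT uninfected replicate 2 or 3, KO uninfected replicate 1 or 2, WT infected replicate 1, 2 or 3, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0617 to 0.388). The mitochondrial list was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1 or 3, WT infected replicate 1, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0535 to 0.263).

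**Figure D1:**
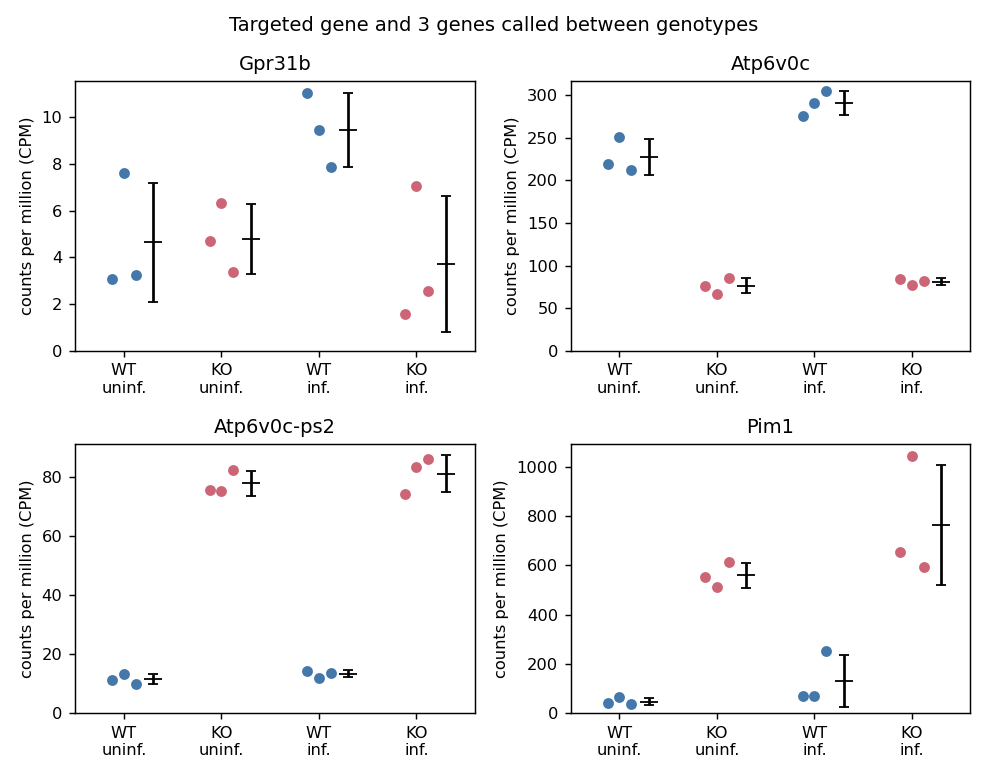
CPM with TMM-scaled library sizes (vertical axes from 0) of Gpr31b, Atp6v0c, Atp6v0c-ps2 and Pim1 in each library of the 4 groups, with points for single libraries (n = 3 per group) and bars for mean ± SD. Atp6v0c stood at 227 ± 20.8 and 291 ± 14.3 in WT against 76.2 ± 8.83 and 81.0 ± 3.80 in KO libraries (uninfected, then infected), while Gpr31b overlapped between uninfected genotypes.

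Between infected genotypes, genes of the cDC1 list were higher and Apoe and the B cell genes Cd79a and Cr2 lower in the libraries labelled KO. Xcr1 (ENSMUSG00000060509) rose from 37.2 ± 18.0 to 149.9 ± 20.8 CPM (SD, n = 3), a log2 change of 2.01 ± 0.33 (adjusted p = 0.0246). The hydrolases Ppt1 and Naaa, both of the cDC1 list, rose by 1.36 ± 0.21 (adjusted p = 0.0206) and 1.27 ± 0.21 (adjusted p = 0.0246). Apoe fell from 1473 ± 397 to 339 ± 153 CPM, or -2.12 ± 0.34 (adjusted p = 0.0231). The B cell receptor component Cd79a fell, at -2.02 ± 0.35 (adjusted p = 0.0437), as did Cr2 at -1.30 ± 0.23 (adjusted p = 0.0499). Ncoa7, a nuclear receptor coactivator, rose by 1.45 ± 0.20 (adjusted p = 0.00759), and Pkig, an inhibitor of protein kinase A, fell, at -1.33 ± 0.24 (adjusted p = 0.0446). Pim1 rose by 2.53 ± 0.40 (adjusted p = 0.0230), with 253 CPM in WT infected replicate 3 against 132 ± 105 in its group. Atp6v0c fell, at -1.84 ± 0.17 (adjusted p = 7.25e-05), and Atp6v0c-ps2 rose, at 2.60 ± 0.24 (adjusted p = 7.25e-05), with the same uncertainty about shared reads.

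As a group, cDC1 genes rose in infected libraries labelled KO with 15 of 15 positive (median 1.36, adjusted p = 4.52e-24, and adjusted p = 0.00752 with an estimated correlation). Of these, 3 passed over all genes and 10 when adjusted over the list alone. B cell genes fell (median -1.33, adjusted p = 2.57e-27), 2 over all genes and 18 when adjusted over the list alone. Plasma cell genes fell (median -1.18, adjusted p = 8.77e-11), 6 of them when adjusted over the list alone. LysoMac and macrophage genes fell (median -0.28, adjusted p = 0.000246), with Apoe called and C1qc at -1.75 ± 0.32 (adjusted p = 0.0519). Under an estimated correlation these lists had an adjusted p of 0.0706 to 0.150. Immediate early genes rose with 27 of 30 positive (median 0.44, adjusted p = 5.21e-07), and dendritic cell maturation genes fell (median -0.24, adjusted p = 0.00399). With an estimated correlation, the adjusted p of these lists ran from 0.271 to 0.619. List medians were -0.77 (plasma cell), -0.0511 (macrophage) and 0.29 (immediate early) without WT infected replicate 2. The macrophage list had a median of -0.18 without KO infected replicate 1 and -0.17 without KO infected replicate 2. The immediate early list had a median of 0.29 without WT infected replicate 1 and 0.72 without WT infected replicate 3. The maturation list had a median of -0.11 without KO infected replicate 1, -0.57 without KO infected replicate 2 and -0.0164 without KO infected replicate 3. The interferon-inducible GTPase Iigp1 differed by 2.69 ± 0.49 (adjusted p = 0.0519) and Jchain, which joins secreted antibodies, by -4.47 ± 0.90 (adjusted p = 0.0741), both short of the threshold.

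In all, 18 of 26620 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 higher and 10 lower in KO, 5 of them immunoglobulin segments. Other tools called 189 with DESeq2 and 90 with limma-voom, and 11 genes were called without receptor segments. Upper-quartile factors gave 10 higher and 8 lower. Atp6v0c and Atp6v0c-ps2 were called with each library left out in turn. Pim1 was lost without WT infected replicate 2, or KO infected replicate 1 or 2 (adjusted p from 0.0563 to 0.146), and Xcr1 without WT infected replicate 2, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0522 to 0.169). Ncoa7 was lost without WT infected replicate 2, or KO infected replicate 1 (adjusted p from 0.0641 to 0.105), Ppt1 without WT infected replicate 2, or KO infected replicate 1 (adjusted p from 0.146 to 0.163) and Naaa without WT infected replicate 2, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0502 to 0.253). Apoe was lost without WT infected replicate 2, or KO infected replicate 1 or 3 (adjusted p from 0.146 to 0.197). Cd79a was lost without KO uninfected replicate 3, WT infected replicate 2, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0522 to 0.337). Pkig was lost without KO uninfected replicate 1, 2 or 3, WT infected replicate 2, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0611 to 0.358). Cr2 was lost without WT uninfected replicate 3, KO uninfected replicate 1, 2 or 3, WT infected replicate 1, 2 or 3, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0515 to 0.369). Gene counts were 4 without WT infected replicate 2, 5 without KO infected replicate 1, 8 without KO infected replicate 3, 31 without WT uninfected replicate 1, 41 without WT uninfected replicate 2, 48 without WT infected replicate 3 and 57 without WT infected replicate 1. Of 36 lists 6 passed, 1 of them with an estimated correlation. The maturation list was lost without WT infected replicate 1, or KO infected replicate 1 or 3 (adjusted p from 0.0603 to 0.582). List counts were 10 without WT infected replicate 1, 12 without WT infected replicate 3 and 15 without KO infected replicate 2.

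**Figure D2:**
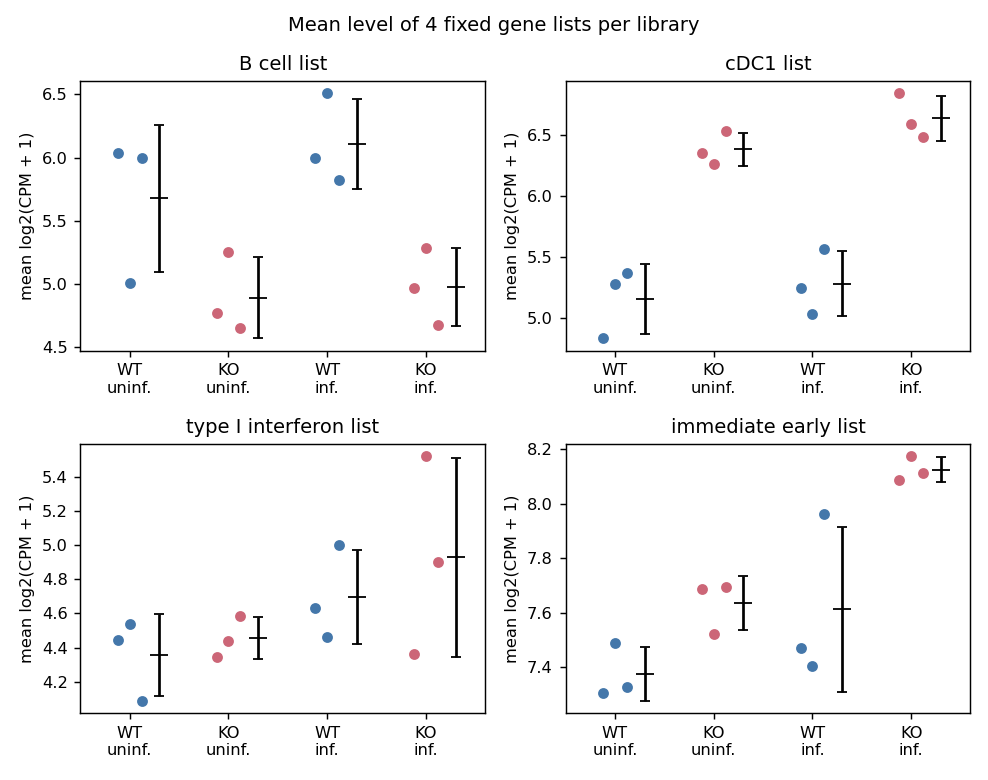
Mean log2(CPM + 1) over the members of the B cell, cDC1, type I interferon and immediate early lists in each library (vertical axes do not start at 0), with points for libraries (n = 3 per group) and bars for mean ± SD. The cDC1 score stood at 5.16 ± 0.29 and 5.28 ± 0.26 in WT against 6.38 ± 0.14 and 6.64 ± 0.18 in KO libraries, and the B cell score at 5.68 ± 0.58 and 6.11 ± 0.36 against 4.89 ± 0.32 and 4.98 ± 0.31 (uninfected, then infected).

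Averaged over infection, libraries labelled KO (n = 6) had higher cDC1 genes and lower B cell and plasma cell genes than WT libraries (n = 6). The cDC1 list rose with 15 of 15 positive (median 1.21, adjusted p = 1.04e-33), and 7 members passed over all genes. They included Tlr3 at 2.64 ± 0.37 (adjusted p = 0.00408), Xcr1 at 1.91 ± 0.23 (adjusted p = 0.000682), Ppt1 at 1.21 ± 0.15 (adjusted p = 0.000678) and the adhesion molecule Cadm1 at 1.16 ± 0.19 (adjusted p = 0.0101). The B cell list fell (median -1.07, adjusted p = 4.52e-36), 8 members over all genes and 20 when adjusted over the list alone. Among them were Cr2 at -1.45 ± 0.17 (adjusted p = 0.000407) and the B lineage gene Vpreb3 at -2.60 ± 0.36 (adjusted p = 0.00405). Cd79a stood at -1.74 ± 0.25 (adjusted p = 0.00408) and the IgM Fc receptor Fcmr at -1.28 ± 0.20 (adjusted p = 0.00677). Plasma cell genes fell (median -0.71, adjusted p = 6.39e-15), with Jchain at -3.71 ± 0.61 (adjusted p = 0.00998) and the syndecan Sdc1 at -2.13 ± 0.36 (adjusted p = 0.0116). With an estimated correlation, the adjusted p of these lists were 0.00308, 0.0335 and 0.0417. Gcsam, which is in both the B cell and cDC1 lists, rose by 1.54 ± 0.27 (adjusted p = 0.0135).

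Genes of chromosome 17 made up 9 of the 89 called between genotypes averaged over infection. Pim1 rose by 3.04 ± 0.29 (adjusted p = 4.95e-05). The molybdenum cofactor enzyme Mocs1 fell, at -2.98 ± 0.46 (adjusted p = 0.00677), as did the salt-inducible kinase Sik1 at -1.46 ± 0.22 (adjusted p = 0.00677) and the ribosomal protein gene Rps2 at -0.83 ± 0.13 (adjusted p = 0.00677). Atp6v0c fell (-1.71 log2) and Atp6v0c-ps2 on chromosome 6 rose, at 2.67 ± 0.17 (adjusted p = 3.5e-07). Hmga1 on chromosome 17 fell (-1.67 log2), while Hmga1b on chromosome 11, which matches it at 99.8% over 1538 bases, rose (1.47 log2). All 4 of these values are uncertain for shared reads. Rftn1, Rnps1 and AC166102.1 made up the rest, and these 3 and the Hmga1 pair were named after their values were seen. Nap1l3 was called (adjusted p = 0.00801), with 0 counts in WT uninfected libraries and no fold given.

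The lysosomal list fell by camera between genotypes averaged over infection (median -0.10, adjusted p = 0.0123, and adjusted p = 0.389 with an estimated correlation). Over all genes 1 member was higher, the saposin precursor Psap at 0.48 ± 0.09 (adjusted p = 0.0254), and 1 lower, the tetraspanin Cd63 at -0.89 ± 0.14 (adjusted p = 0.00732). Adjusted over the list alone, 2 were higher and 5 lower. The asparaginyl protease gene Lgmn fell, at -1.28 ± 0.20 (adjusted p = 0.00677), and the endosomal Rab7b rose by 1.60 ± 0.32 (adjusted p = 0.0334). Ifi205, an interferon-inducible gene of the cDC1 list, rose by 1.69 ± 0.29 (adjusted p = 0.0137). The germinal centre factor Mef2b fell, at -2.30 ± 0.47 (adjusted p = 0.0460), as did the kinases Pim2 at -2.08 ± 0.40 (adjusted p = 0.0284) and Srpk3 at -1.75 ± 0.33 (adjusted p = 0.0270). Lower too were the lymphoid surface genes Ly6d at -1.66 ± 0.30 (adjusted p = 0.0205) and Cd2 at -1.67 ± 0.33 (adjusted p = 0.0334). The macrophage list fell (median -0.16, adjusted p = 0.00235), with Apoe at -1.54 ± 0.23 (adjusted p = 0.00677) and C1qb at -1.05 ± 0.22 (adjusted p = 0.0476). Its adjusted p with an estimated correlation was 0.224. Immediate early genes rose (median 0.29, adjusted p = 2.74e-06), 7 higher and 1 lower when adjusted over the list alone. Cell cycle (median -0.30, adjusted p = 8.01e-06), epithelial (median -0.83, adjusted p = 0.000824) and ribosomal protein genes (median -0.11, adjusted p = 0.00162) fell. For these 4 lists, an estimated correlation gave an adjusted p of 0.224 to 0.735. Over all tested genes the median genotype effect was 0.14 under 5 CPM, 0.00270 from 5 to 30, -0.0741 from 30 to 100 and -0.0456 at 100 CPM or more. Whether background reads differing between genotypes gave the effect under 5 CPM was not tested. Leaving out WT infected replicate 3 gave medians of -0.26 (macrophage), -0.0299 (lysosomal), 0.47 (immediate early) and -0.19 (ribosomal). With WT uninfected replicate 3 left out, the medians were -0.27 (macrophage), -0.0643 (lysosomal) and -0.13 (cell cycle). List medians were -0.0920 (macrophage), -0.0678 (lysosomal) and -0.0202 (ribosomal) without WT infected replicate 2. The macrophage list had a median of -0.29 without KO uninfected replicate 3. The lysosomal list had a median of -0.0647 without KO uninfected replicate 1 and -0.0576 without KO infected replicate 1. The cell cycle list had a median of -0.19 without KO uninfected replicate 3. The epithelial list had a median of -0.20 without WT uninfected replicate 1. The ribosomal list had a median of -0.0652 without WT infected replicate 1 and -0.050 without KO infected replicate 2.

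Lower by small medians averaged over infection were also oxidative phosphorylation (median -0.17, adjusted p = 0.00107), cholesterol synthesis (median -0.18, adjusted p = 0.00565), cholesterol efflux (median -0.11, adjusted p = 0.0362), the unfolded protein response (median -0.13, adjusted p = 0.00107) and dendritic cell maturation (median -0.12, adjusted p = 0.0123). Under an estimated correlation these 5 lists had an adjusted p of 0.224 to 0.627. Leaving out WT infected replicate 2 gave medians of -0.0938 (oxidative phosphorylation), -0.0989 (cholesterol synthesis), -0.23 (cholesterol efflux) and -0.0658 (maturation). With WT infected replicate 1 left out, the medians were -0.0615 (cholesterol efflux), -0.21 (unfolded protein response) and -0.0577 (maturation). The cholesterol efflux list had a median of -0.0610 without WT uninfected replicate 1, -0.0734 without WT uninfected replicate 2, -0.17 without WT uninfected replicate 3, -0.24 without KO uninfected replicate 2, -0.0251 without KO uninfected replicate 3, -0.0136 without KO infected replicate 1 and -0.21 without KO infected replicate 3. The unfolded protein response list had a median of -0.27 without KO infected replicate 2. The maturation list had a median of -0.0778 without WT uninfected replicate 1, -0.18 without WT infected replicate 3, -0.0437 without KO infected replicate 1, -0.27 without KO infected replicate 2 and -0.00773 without KO infected replicate 3. Dendritic cell maturation was lost without WT uninfected replicate 1, KO uninfected replicate 2, WT infected replicate 1, or KO infected replicate 1 or 3 (adjusted p from 0.0533 to 0.368). Cholesterol efflux was lost without WT uninfected replicate 3, KO uninfected replicate 1, WT infected replicate 2 or 3, or KO infected replicate 1 or 3 (adjusted p from 0.0505 to 0.122). Cholesterol synthesis was lost without KO uninfected replicate 3, or WT infected replicate 1 or 2 (adjusted p from 0.0563 to 0.0749).

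By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 89 of 26620 genes were called between genotypes averaged over infection, 22 higher and 67 lower in KO, 16 of them receptor segments. Other tools called 290 with DESeq2 and 106 with limma-voom. Of 36 lists 16 passed, and cDC1, B cell and plasma cell genes passed with an estimated correlation and by fry. Gene calls fell to 3 with the B cell score as a covariate, chosen after seeing the data. In that fit Xcr1 stood at 1.43 ± 0.39 (adjusted p = 0.996), Apoe at -0.83 ± 0.33 (adjusted p = 0.996), Pim1 at 2.49 ± 0.43 (adjusted p = 0.136) and Atp6v0c-ps2 at 2.43 ± 0.29 (adjusted p = 0.00358). The B cell, cDC1 and LysoMac scores together gave Pim1 at 0.55 ± 1.56, Apoe at -0.75 ± 1.27, Xcr1 at 1.66 ± 0.91 and Atp6v0c-ps2 at 3.05 ± 1.06, each with an adjusted p of 1. The B cell and cDC1 scores differ by genotype, the cDC1 score without overlap, so neither fit can separate a score from genotype. Xcr1 is also a member of the cDC1 list and Apoe of the LysoMac list. Gene counts were 31 without KO uninfected replicate 1, 34 without KO uninfected replicate 3, 37 without KO infected replicate 1, 39 without KO infected replicate 3, 50 without WT infected replicate 2, 59 without WT uninfected replicate 1 and 153 without WT uninfected replicate 2. Gcsam and Jchain were lost without KO uninfected replicate 1 or 3 (adjusted p from 0.0523 to 0.0568). Ifi205 was lost without KO uninfected replicate 3, or KO infected replicate 3 (adjusted p from 0.0533 to 0.0543), and Sdc1 without KO uninfected replicate 1 or 3, or KO infected replicate 3 (adjusted p from 0.0542 to 0.0555). Rab7b was lost without WT uninfected replicate 1 or 2, KO uninfected replicate 1, 2 or 3, or KO infected replicate 1 or 3 (adjusted p from 0.0543 to 0.142). Psap was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1, 2 or 3, or KO infected replicate 1, 2 or 3 (adjusted p from just over 0.05 to 0.0999). C1qb was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1, 2 or 3, WT infected replicate 2 or 3, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0597 to 0.192). Mef2b was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1, 2 or 3, WT infected replicate 2, or KO infected replicate 1, 2 or 3 (adjusted p from 0.0696 to 0.202). Pim2 was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1, 2 or 3, WT infected replicate 2, or KO infected replicate 1 or 3 (adjusted p from 0.0542 to 0.126). Srpk3 was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1 or 3, WT infected replicate 2, or KO infected replicate 1 or 3 (adjusted p from 0.0635 to 0.112). Ly6d was lost without WT uninfected replicate 1, KO uninfected replicate 1 or 3, WT infected replicate 2, or KO infected replicate 1 or 3 (adjusted p from 0.0593 to 0.0947). Cd2 was lost without WT uninfected replicate 1 or 3, KO uninfected replicate 1, 2 or 3, WT infected replicate 2 or 3, or KO infected replicate 1, 2 or 3 (adjusted p from just over 0.05 to 0.137). The epithelial list was lost without WT uninfected replicate 1 (adjusted p = 0.0836), and the ribosomal list without WT infected replicate 2 (adjusted p = 0.417). The lysosomal list was lost without WT uninfected replicate 2, WT infected replicate 3, or KO infected replicate 1 (adjusted p from 0.0613 to 0.102).

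The interaction asked whether infection acted differently in the libraries labelled KO, the question closest to the title of the study. Cell cycle genes had a higher infection effect in KO than in WT, with 28 of 33 members positive (median difference 0.29 log2, adjusted p = 0.0487). The adjusted p was 0.918 with an estimated correlation. The median infection effect on this list was -0.08 in WT (adjusted p = 0.461) and 0.21 in KO (adjusted p = 0.000762, or 0.30 with an estimated correlation). The replication licensing factor Mcm3 differed by 0.94 ± 0.30, the transcription factor E2f1 by 1.37 ± 0.71, the mitotic kinase Plk1 by 1.48 ± 0.82 and Mki67 by 0.77 ± 0.43, none past the threshold. The cell cycle list had a median of 0.15 without WT uninfected replicate 3, 0.49 without WT infected replicate 2, 0.16 without WT infected replicate 3 and 0.15 without KO infected replicate 2. The macrophage genes C1qc (-1.45 ± 0.44) and Apoe (-1.16 ± 0.46) and the interferon-inducible GTPase Iigp1 (2.47 ± 0.67) did not pass either. The type I interferon list was raised in each genotype by camera, with an adjusted p of 0.484 in WT and 0.143 in KO with an estimated correlation. Its difference between the genotypes did not pass (median 0.32, adjusted p = 0.422). Neither did those of the interferon-gamma (median 0.22, adjusted p = 0.208), cytokine (median 0.26, adjusted p = 0.510) and immediate early lists (median 0.15, adjusted p = 0.144).

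For the interaction, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 26620 genes. At an unadjusted p under 0.05 there were 1103 (1331 by chance), and other tools called 11 with DESeq2 and 0 with limma-voom. Without WT infected replicate 1 it called 1. The cell cycle call was lost without WT uninfected replicate 3, KO uninfected replicate 1 or 3, WT infected replicate 1 or 3, or KO infected replicate 2 (adjusted p from 0.0501 to 0.341). List counts were 0 without KO uninfected replicate 1, 2 without WT infected replicate 1, 3 without KO infected replicate 1, 4 without WT uninfected replicate 1, or KO uninfected replicate 3, 5 without WT infected replicate 2 and 6 without KO infected replicate 2. Across the 11189 genes with at least 10 CPM, which are not independent replicates, the infection effects in WT and KO correlated at r = 0.217 (Spearman rho 0.205). The genotype effects in uninfected and infected libraries correlated at r = 0.338 (rho 0.193), and neither pair of effects shared libraries. Of the 6 and 18 genes called between genotypes in uninfected and infected libraries, 5 were called in the same direction in both, where independent lists would share 0.00195. These lists were not independent, because both contrasts used the same dispersion per gene. Atp6v0c and Atp6v0c-ps2, called in both, may also share reads. The expected value is therefore no measure of replication.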

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

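The count of splits was chosen after the result was seen, and the interaction and the libraries left out were fixed earlier. The cell cycle list stood out because the effect of infection differed between genotypes by a test of the difference itself, at a camera adjusted p of 0.0487 with a median difference of 0.29 log2 and 28 of 33 members positive. With an estimated correlation the adjusted p was 0.918. The list score went from 5.55 ± 0.33 to 5.34 ± 0.42 with infection in WT and from 5.08 ± 0.27 to 5.19 ± 0.21 in KO-labelled libraries (SD, n = 3). The uninfected KO libraries were the lowest group, with a genotype effect of -0.49 there (adjusted p = 2.62e-08, and 0.262 with an estimated correlation). The call was lost without WT uninfected replicate 3, KO uninfected replicate 1 or 3, WT infected replicate 1 or 3, or KO infected replicate 2 (adjusted p from 0.0501 to 0.341). The cell cycle list had a median of 0.15 without WT uninfected replicate 3, 0.49 without WT infected replicate 2, 0.16 without WT infected replicate 3 and 0.15 without KO infected replicate 2. Of 100 drawn splits of the libraries, 97 gave at least as many passing lists as the real 1, with 19 as the highest of the others. Such splits bring the genotype effect into the contrast, so their counts show no value free of change, and chance is left open.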

How the results depend on the processing

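The covariate, 30 CPM and chromosome 17 alternatives were chosen after seeing the data; the others were planned. Counts are given in the order infection in WT, infection in KO, genotype in uninfected, genotype in infected, averaged genotype and interaction. The main counts of called genes were 0, 0, 6, 18, 89, 0, and RLE factors (0, 0, 6, 18, 86, 0) and upper-quartile factors (0, 0, 6, 18, 81, 0) moved none of them by over 1.5 times. Without a filter on low counts there were 235, 62, 124, 292, 393, 50, with DESeq2 146, 15, 52, 189, 290, 11, with limma-voom 0, 8, 4, 90, 106, 0 and with a mean of at least 30 CPM 0, 3, 7, 89, 129, 0. Robust empirical Bayes and the test without receptor segments each called 1 gene for infection in KO, and a fit of only the groups compared called 14. That last fit took its dispersion, filter and scaling from the KO libraries alone. The test without receptor segments called 11 for genotype in infected, and the test without chromosome 17 called 3 for genotype in uninfected. With the B cell score as a covariate there were 0, 2, 2, 1, 3, 0, and with the B cell, cDC1 and LysoMac scores 0, 0, 0, 1, 1, 0. Apart from the smaller set of genes tested without chromosome 17 or receptor segments, the cause was not tested.

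Replicate numbers were shared between groups, but only as numbers. Deviations of the 18 same-numbered pairs correlated at r from -0.0891 to 0.0887 across genes, with 0 above 0.1. With the replicate block the gene counts were 0, 0, 3, 13, 72, 0 and the list counts 17, 21, 12, 6, 17, 1, so the block moved the count for genotype in uninfected to 3 and no other by over 1.5 times.

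The main counts of lists were 16, 21, 12, 6, 16, 1. Camera with an estimated correlation gave 0, 0, 1, 1, 3, 0, fry 0, 0, 1, 1, 3, 0, a mean of at least 30 CPM 7, 6, 9, 6, 6, 4, the B cell covariate 16, 21, 7, 5, 10, 1 and the 3 scores as covariates 1, 15, 0, 1, 0, 3. For genotype in infected, no filter and limma-voom each gave 11. For the interaction, limma-voom gave 5, the filter of 5 CPM 2, and RLE factors and the test without chromosome 17 0. The cause was not tested.

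Leaving out each library in turn gave 0 to 11 genes for infection in WT, 0 to 4 for infection in KO, 3 to 9 for genotype in uninfected, 4 to 57 for genotype in infected, 31 to 153 for averaged genotype and 0 to 1 for the interaction. Lists ran from 6 to 15 for genotype in infected and from 0 to 6 for the interaction. Some lists passed in the other direction without 1 library. Without WT infected replicate 3 these were, for infection in WT, the ribosomal (median -0.19 to 0.16 over the libraries left out) and mitochondrially encoded lists (-0.37 to 0.13). Without KO infected replicate 2 they were dendritic cell maturation for infection in KO (-0.25 to 0.47), the interferon-gamma (-0.16 to 0.37) and NF-kB lists (-0.15 to 0.0966) for genotype in infected, and, by camera's direction with medians that stayed positive, the interferon-gamma list for averaged genotype (0.0395 to 0.19).

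Covariates turned the tested direction of further lists and genes, given as log2 medians or changes. For lists this is camera's direction, and some medians kept their sign, as for conventional dendritic cell 2 with 3 scores. With the B cell score, for genotype in uninfected these were immediate early at -0.0825, mitochondrially encoded at 0.14. For genotype in infected these were dendritic cell maturation at 0.0993, cell cycle at 0.31, mitochondrially encoded at 0.51. For the averaged genotype effect these were Pim2 at 0.0650, dendritic cell maturation at 0.23, conventional dendritic cell 2 at -0.14, plasmacytoid dendritic cell at 0.12, immediate early at -0.0141, cell cycle at 0.10, mitochondrially encoded at 0.30. With 3 scores, for infection in WT these were plasma cell at -0.00747. For genotype in uninfected these were cDC1 at -0.19, epithelial at 2.34, immediate early at -0.17, mitochondrially encoded at 1.20. For genotype in infected these were dendritic cell maturation at 0.10, cDC1 at 0.0632, immediate early at -0.41, mitochondrially encoded at 1.43. For the averaged genotype effect these were Ifi205 at -0.59, Vpreb3 at 0.59, Psap at -0.0982, Ppt1 at -0.12, Ly6d at 0.24, dendritic cell maturation at 0.33, cDC1 at -0.12, conventional dendritic cell 2 at 0.29, plasmacytoid dendritic cell at 0.83, epithelial at 1.59, immediate early at -0.27, cell cycle at 0.00439. The 3 scores leave 5 residual degrees of freedom and are built from listed genes, so the cDC1 list was adjusted for its own score. The cDC1 score did not overlap between genotypes, so the fit cannot separate it from genotype. The cause of these turns was not tested further. Of genes under 10 CPM changed 4-fold, 2 of 25 were recovered in simulated data for infection in WT, at the one depth and number of mice used.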

Other observations

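Chosen only after the results were seen were the tests of chromosome 17 genes, of the main cell type's share, of B lineage markers, of background reads and of splits, the covariate, and the reading of lists within the matched range. Gene groups tied to the known action of GPR31, the extension of dendrites under lactate and pyruvate, showed no genotype effect that passed. Actin and protrusion genes had a median of -0.09 averaged over infection (adjusted p = 0.189), with the small GTPase Rac2 at -0.76 ± 0.16 (adjusted p = 0.0526) and the kinase Pak1 at 0.43 ± 0.17 (adjusted p = 0.535). Glycolysis and lactate transport stood at 0.03 (adjusted p = 0.789), and cAMP and CREB-responsive genes at 0.02 (adjusted p = 0.835), where Sik1 alone was called. The LysoDC identity list scored 6.09 ± 0.05, 6.25 ± 0.07, 6.20 ± 0.16 and 6.26 ± 0.15 in WT uninfected, WT infected, KO uninfected and KO infected libraries (averaged genotype effect 0.12, adjusted p = 0.537). Neither the type I interferon (adjusted p = 0.341) nor the interferon-gamma list (0.691) differed between genotypes by camera, and Iigp1 was at 1.46 ± 0.33 (adjusted p = 0.0888).

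Further marker lists passed between genotypes averaged over infection. The conventional dendritic cell 2 list rose in KO by 0.30 (adjusted p = 0.0137, and 0.389 as an adjusted p with an estimated correlation), lost without WT uninfected replicate 1 or 3, or WT infected replicate 2 (adjusted p from 0.0689 to 0.121). The plasmacytoid list fell at -0.30 (adjusted p = 0.0290, and 0.241 as an adjusted p with an estimated correlation), lost without WT uninfected replicate 1 or 3, KO uninfected replicate 3, WT infected replicate 2, or KO infected replicate 1 or 3 (adjusted p from 0.0523 to 0.0884). The plasmacytoid list had a median of -0.20 without WT uninfected replicate 1, -0.17 without WT infected replicate 1 and -0.14 without KO infected replicate 3. Lists of T, NK and innate lymphoid cells (adjusted p = 0.266), neutrophils (0.838) and stroma (0.998) did not pass. Autophagy (0.149), pattern recognition (0.691, with Tlr3 called) and the neighbours of Gpr31b (0.266) did not pass either. The complement list missed with a negative test and a median of 0.04 (adjusted p = 0.0658). In infected libraries, Spp1, a secreted glycoprotein of macrophages, differed between genotypes by -4.20 ± 1.28 (adjusted p = 0.379), and the macrophage scavenger receptor Msr1 by -1.09 ± 0.32 (adjusted p = 0.348).

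The first pattern is the excess of chromosome 17 genes among those called between genotypes, 9 of 73 called genes other than receptor segments (12.3%) against 1216 of 26418 others (4.60%, Fisher's exact two-sided p = 0.00638). A segment of another strain kept around the targeted gene could give such an excess, with expression variants at Pim1, Sik1, Mocs1 and Rps2. The test covered the whole chromosome without gene positions, so it cannot place these genes near Gpr31b. No strain is given in the sources used here, and an effect of the receptor on these genes stays open, as untested. Among genes called higher, 2 of 22 (9.09%) matched the transcript of a gene called lower, against 77 of 26404 (0.292%, Fisher's exact p = 0.00196), so that shared reads may explain Atp6v0c-ps2 and Hmga1b, with a variant in the chromosome 17 gene as a candidate source. Summed over both members, Atp6v0c and its copy still fell from 272 ± 39.3 to 158 ± 9.61 CPM (SD, n = 6, exact p = 0.005, the smallest possible), and Hmga1 with Hmga1b from 49.5 ± 7.87 to 37.0 ± 8.11 (exact p = 0.03). Moved reads within these pairs therefore leave a lower sum open to reads lost to further copies or to a true change.

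The second pattern is the lower B and plasma cell lists and the higher cDC1 list in libraries labelled KO. A lower share of the main cell type alone would move other markers alike. With an estimated correlation 1 list rose (cDC1) and 2 fell (B and plasma cell), which such a shift alone would not give. These lists define the pattern, so this is no separate test, and mixed changes of cell types stay open. Cells or RNA of the B lineage in the sorted pools may account for the lymphoid part, although the FACS gate was meant to remove such cells. Within groups the B cell score (25 genes) and the receptor segment share deviated together (Pearson r = 0.949, exact one-sided permutation p = 0.00463 against a smallest possible 0.000772, rho = 0.825, p = 0.00849, and r = 0.913 without the 2 farthest libraries). Both measures read B lineage RNA, so they show that its amount varied within groups. They cannot show why the genotypes differ. With the B cell score as a covariate, Xcr1 went from 1.91 ± 0.23 to 1.43 ± 0.39 (adjusted p = 0.996) and Apoe from -1.54 ± 0.23 to -0.83 ± 0.33 (adjusted p = 0.996). Pim1 went from 3.04 ± 0.29 to 2.49 ± 0.43 (adjusted p = 0.136) and Atp6v0c-ps2 from 2.67 ± 0.17 to 2.43 ± 0.29 (adjusted p = 0.00358). None of these genes is a member of the B cell list. The score is itself lower on average in KO-labelled libraries, so the fit cannot separate B cell content from genotype. Smaller changes with larger errors do not decide between them. Whether the genotypes differ in the cells that enter the gate, or in cDC1 numbers, stays open, as 3 of the 15 cDC1 markers are also in other lists and no cell counts were used here.

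The third pattern is the rise of many lists at once with infection, where in both genotypes the median log2 change also rose with level, from -0.26 under 5 CPM to 0.16 at 100 CPM or more in WT and from -0.25 to 0.20 in KO. Counts over sensory receptor genes, as CPM per kb, were 0.966 ± 0.125 in uninfected and 0.711 ± 0.128 in infected libraries (SD, n = 6, exact two-sided permutation p = 0.01 within genotype, smallest possible 0.005), so fewer background reads after infection could produce such a trend. Of the passing lists, 8 of 16 in WT and 12 of 21 in KO had medians above the central 95% of 10000 random lists matched on level. The type I interferon and immediate early lists were among them. The lists were chosen for passing as higher on the same fold changes, and random genes were drawn independently. These counts therefore cannot exclude the trend as the whole cause. Of all these lists 0 passed with an estimated correlation. Without KO infected replicate 2 the interferon-gamma, cytokine, NF-kB and B cell medians in KO were 0.12, -0.00024, 0.10 and 0.00766. LysoDC identity stood at 0.16 and type I interferon at 0.37 there, with matched random medians over all libraries of 0.15 and 0.074. Without WT infected replicate 3 the immediate early median in WT was 0.18, with a matched random median over all libraries of 0.15. The trend therefore stays open for lists above the matched range too. The remaining 8 and 9, MHC class II and oxidative phosphorylation among the latter, cannot be told apart from the level trend, because their medians lie within the matched range. The unfolded protein response in KO, at 0.14, lay under its matched random median of 0.18.

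Other splits of the same libraries were counted for each result. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. Of these, 10 gave at least the 0 genes called for infection in WT (highest other 2) and 10 the 0 genes for infection in KO (highest other 0), while the 16 and 21 lists were reached by 1 split each, the real one (highest other 10 and 17). Between genotypes, 1 split gave the 6 genes in uninfected (highest other 0), 1 the 12 lists (highest other 10), 1 the 18 genes in infected (highest other 0) and 8 the 6 lists (highest other 20). The split with 20 set WT infected replicates 2 and 3 with KO infected replicate 2 against the rest, and what these share is open. For averaged genotype, 1 of 100 drawn splits, the real one, reached 89 genes, the smallest share that 100 splits allow. This argues against chance for the gene count, but 100 splits counted after the result was seen cannot exclude it. The highest other, 60, exchanged only WT uninfected replicate 2 with KO uninfected replicate 2. The 16 lists were reached by 6 of 100 (highest other 19), so chance is not excluded. For the interaction 100 of 100 splits reached 0 genes, and 97 of 100 reached 1 list (highest other 19). The highest other of genes, 89, exchanged the genotypes of all infected libraries, which turns the contrast into the averaged genotype effect. As such splits bring the genotype effect into the contrast, chance is left open for the interaction.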
